A study of Mus musculus with 6 samples.

How the data were processed

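Gene expression was measured by poly-A RNA sequencing of mouse liver cells taken at week 0, week 2 or week 7 of a treatment that the series title names as MET/CAT and SB transposase. A transposase moves DNA flanked by its recognition ends into a genome; the labels do not expand CAT. Each week is represented by 2 libraries, 6 in all. The label of week 0 replicate 1 gives a line of mixed FVB/N and C57BL/6 background, and in the labels of the other samples the number after C57BL/ differs, rising by 2 from sample to sample, so their background is unsure. The groups and replicate numbers were taken from the sample titles.

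Per the labels' protocols, poly-A RNA was enriched from total RNA, libraries were made with the TruSeq V2 kit and paired ends were sequenced. The submitters' processing notes list Bowtie 0.12.2 and the mouse build mm8, with no role for either. The counting program, its settings and the annotation are not given in the sources used here. The deposited table holds estimated counts per Ensembl gene, not scaled to depth, for 54446 genes and all 6 libraries. All values were whole, so rounding changed 0 of them. Of the gene identifiers, 54409 were matched to symbols of the GENCODE M21 annotation, and those without a match held at most 0.00079% of the counts of a library. Some identifiers postdate mm8, so the build behind the table is unsure and no coordinates are given.

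The low values of the table are stepped. Of the values from 4 to 43, between 68.3% and 69.6% per library were a multiple of 4 or lay 1 above it. The share would be 50.0% if all these values were equally frequent. A higher frequency of the lowest values would raise it without any steps, by an amount that was not tested. A read pair was assumed to be worth about 4 deposited counts, and library totals ran from 49353453 to 58434358 deposited counts. A fold against a group with 0 counts is given as a lower bound, computed against a floor of 12 counts (3 read pairs) in each library, averaged over the group after TMM scaling, or 0.245 CPM at week 0, 0.201 at week 2 and 0.228 at week 7. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. Reads of near-identical genes, as in the Cyp2, Cyp3a, Cyp4a, Sult and Mup families, may have been split in ways the table does not show, so single members are uncertain. The kit does not mark strand, so antisense genes are not described.

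Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr on the groups, which left 15368, and libraries were scaled with TMM. A robust quasi-likelihood model with 1 coefficient per week was fitted to all 6 libraries (3 residual degrees of freedom, common biological coefficient of variation 0.209), and each pair of weeks was tested 2-sided, as was any difference over the 3 weeks. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was a call. Levels are TMM-scaled CPM (deposited counts relative to 1e6 counts of library size), given as mean ± SD over 2 libraries, and plain folds are ratios of those means. Lists of genes, 32 in number with 434 tested members, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. They cover Wnt and receptor signalling, liver zonation and metabolism, sex-biased genes, stress and inflammatory responses, tumour markers, proliferation, matrix and 9 other cell types. List tests were repeated with an estimated correlation and with fry, which asks whether a list moves on balance in 1 direction. The estimated correlation called no list in any comparison. It missed even male-biased genes at week 2, of which all 13 fell (camera adjusted p = 0.0838). A call lost this way therefore does not tell weak lists from strong ones. Library checks used Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

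The tests, the lists and the rule for named genes were chosen before the data were examined. The rule takes 10 panel genes whatever their result. For each comparison it adds the 8 higher and 8 lower called genes with the largest fold change, with a gene symbol of the usual kind, groups that do not overlap and a mean of at least 5 CPM in the higher group. For each list it adds up to 2 called members in each direction by adjusted p, or the 2 with the smallest p where none was called. Genes named outside the rule are said to have been chosen after their values were seen.

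Alternatives were other scalings (median-of-ratios, upper-quartile, total counts only), no filter, a minimum of 10 counts in every library of a group, DESeq2 1.42.0, limma voom, only the 4 libraries compared, a replicate block, each library left out in turn, an adjusted p under 0.01 and a test against a fold change of 1.5. After the data were seen, counts divided by 4 and a fit without the week 2 libraries were added. The methods were tested on simulated data drawn from the real week 0 means and library sizes, over 15368 genes. The changed genes were taken among those with at least 5 CPM at week 0. Recovery at lower levels was therefore not tested, and Afp, Gpc3, Lgr5 and Axin2 were below that level at week 0. For week 7 against week 0, 83 of 100 genes changed by 2-fold and 95 of 100 changed by 4-fold were recovered with 13 false calls, and for week 2 against week 0 the numbers were 82, 95 and 9. In the simulated comparison of week 7 with week 0, camera called the planted list (adjusted p = 9.81e-23) and 0 of 30 unchanged lists. The simulated genes were drawn independently and the unchanged lists at random. False calls for lists whose genes vary together were therefore not tested.

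Nothing in the labels says that the 2 libraries of a week came from separate animals, so p-values measure the spread between these libraries only, which may be technical.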

Results

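The data are gene counts from 6 mouse liver libraries, 2 from each of weeks 0, 2 and 7 of treatment. Library totals were 51758582 and 49353453 deposited counts at week 0, 58434358 and 56857344 at week 2, and 53952382 and 51627088 at week 7. The 10 most abundant genes took 21.3% to 22.7% of the counts of a library, and mitochondrial genes took 6.1% to 7.6%. Transcripts of the major urinary protein (Mup) genes, which liver makes in larger amounts in male than in female mice, took 10.4% and 10.1% at week 0, 2.94% and 2.83% at week 2, and 10.4% and 11.5% at week 7. Albumin transcripts took 6.36% in both week 0 libraries, 10.1% and 9.65% at week 2, and 5.41% and 5.39% at week 7.

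Genes that mark sex separated week 2 from the other weeks. Xist, the X-inactivation RNA of female cells, had 13236 and 12804 counts in the week 2 libraries, 10 and 15 at week 0, and 0 and 0 at week 7. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 0 counts in both week 2 libraries. Ddx3y had 2113 and 1897 counts at week 0 and 2045 and 2303 at week 7. The week 2 libraries were thus typed as female and the others as male. Week 7 against week 0 is the comparison in which sex does not differ, and both comparisons with week 2 differ in time and in sex together. The libraries include no untreated mice at weeks 2 or 7. Age, the unsure strain background and anything else that goes with the week can therefore not be told apart from treatment in any comparison.

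**Figure D1:**
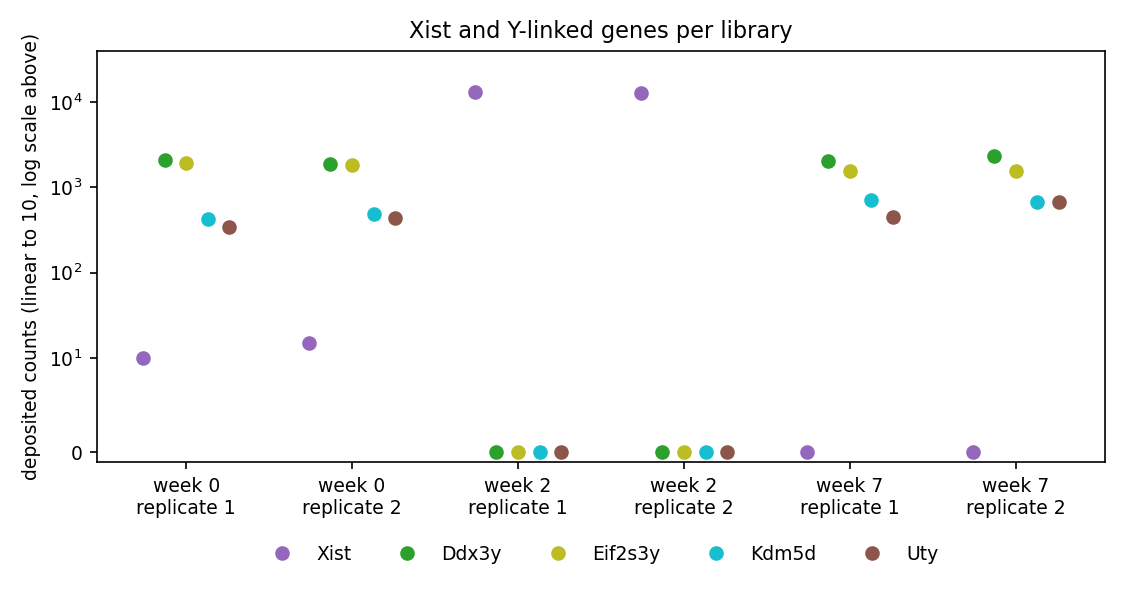
Deposited counts of Xist and 4 Y-linked genes (y axis, linear to 10 and logarithmic above) in each of the 6 libraries (x axis), 1 point per gene and library. Xist lies at 13236 and 12804 in the week 2 libraries and at or below 15 in the others, and the Y-linked genes are at 0 in week 2 only.

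Libraries of the same week were close to each other. Among genes with over 6400 read pairs in a pair of libraries, the log2 difference between replicates had a robust SD of 0.0522 at week 0, 0.0524 at week 2 and 0.0755 at week 7, where counting alone gives 0.0264, 0.0268 and 0.0263. The first libraries of different weeks differed by 0.247 to 0.37 on the same measure. Replicates thus differed by more than counting error, which does not show that they came from separate animals. Each library was kept as its own replicate.

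Between week 0 and week 7, 10 of 17 fetal liver and tumour markers, 12 of 14 Wnt target genes and 13 of 16 hepatocyte genes of the central vein region rose. Their list calls were lost with an estimated correlation (adjusted p = 0.164, 0.122 and 0.122). Afp (ENSMUSG00000054932), which encodes the fetal serum protein alpha-fetoprotein, went from 0.418 ± 0.00428 to 104 ± 1.13 CPM (SD, n = 2). Its log2 fold change was 7.95 (edgeR adjusted p = 9.21e-09), with 41 deposited counts over both week 0 libraries. Gpc3 (ENSMUSG00000055653), which encodes the surface proteoglycan glypican 3, rose from 0.328 ± 0.123 to 17.3 ± 1.501 CPM (adjusted p = 1.42e-05). Glul (ENSMUSG00000026473), which encodes glutamine synthetase, rose 4.58-fold from 341 ± 12.2 to 1560 ± 0.906 CPM (adjusted p = 4.33e-09). Of the unfolded protein response genes 9 of 15 fell, as did 6 of 7 markers of Kupffer cells, the resident macrophages of liver (adjusted p = 0.164 for each list with an estimated correlation).

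The Wnt feedback list had 12 risen and 0 fallen genes among 14 measured, the same 12 and 0 adjusted over the list alone, with a median log2 fold change of 2.29 (camera adjusted p = 3.54e-09; adjusted p = 0.122 with an estimated correlation). Axin2 (ENSMUSG00000000142), a negative regulator of beta-catenin, rose 4.38-fold from 3.88 ± 0.613 to 17.0 ± 2.68 CPM (edgeR adjusted p = 0.000155). Lgr5 (ENSMUSG00000020140), a receptor for R-spondins, rose 8.78-fold from 1.15 ± 0.159 to 10.1 ± 2.62 CPM (adjusted p = 0.000157), and Nkd1, an inhibitor of Wnt signalling, rose 13.7-fold from 3.90 ± 0.640 to 53.2 ± 2.53 CPM (adjusted p = 5.79e-07). Among 16 pericentral hepatocyte genes 13 rose and 1 fell, or 15 and 1 adjusted over the list alone, with a median of 1.09 (camera adjusted p = 2.49e-12; adjusted p = 0.122 with an estimated correlation). Beside Glul, the glutamate transporter gene Slc1a2 rose 5.11-fold from 58.1 ± 1.95 to 297 ± 7.44 CPM, and Rgn, the member that fell, went from 1157 ± 20.4 to 1049 ± 39.1 CPM (adjusted p = 0.0275). The Rgn call was lost with total counts only (adjusted p = 0.0703), the replicate block (0.0654) and only the 4 libraries compared (0.0775). It was also lost without week 0 replicate 1 or 2, week 2 replicate 1 or 2 or week 7 replicate 1. The log2 fold changes were then -0.1223, -0.157, -0.1397, -0.1388 and -0.1011, against -0.1402. The periportal list moved both ways, with 4 risen and 3 fallen of 16 (5 and 5 adjusted over the list alone; camera adjusted p = 0.839). Its members Apoa4 and Ass1 went from 220 ± 14.8 to 546 ± 1.52 CPM and from 2791 ± 1.43 to 2411 ± 30.02 CPM, both called.

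Of 17 measured oncofetal and liver tumour markers, 10 rose and 0 fell, or 10 and 2 adjusted over the list alone. Their median log2 fold change was 3.87, or 2.60 with genes at 0 counts set to their bound (camera adjusted p = 7.75e-06; adjusted p = 0.164 with an estimated correlation). Ly6d rose from 0.471 ± 0.213 to 24.9 ± 0.488 CPM, and Dlk1, a Notch-family surface protein of fetal liver, had 0 counts at week 0 and 6.58 ± 1.09 CPM at week 7, at least 26.9-fold higher. The list of genes induced by receptor tyrosine kinase to ERK signalling had 10 risen and 0 fallen of 15, the same adjusted over the list alone, with a median of 1.06 (camera adjusted p = 6.08e-05; adjusted p = 0.164 with an estimated correlation). Phlda1 rose 8.07-fold from 43.7 ± 3.91 to 353 ± 12.6 CPM, and Spry4, a feedback inhibitor of the pathway, rose 3.99-fold from 6.06 ± 0.0115 to 24.2 ± 0.768 CPM.

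The receptor gene Met (ENSMUSG00000009376) had 34.8 ± 0.642 CPM at week 0 and 62.96 ± 21.98 CPM at week 7, a difference that was not called (adjusted p = 0.103). Its week 7 libraries lay apart, at 47.42 and 78.51 CPM. The log2 fold change of Met was 0.857, or 1.178 without week 7 replicate 1 and 0.450 without week 7 replicate 2. Fits with 1 week 7 library lack the spread that kept Met from a call, so they cannot decide it. DESeq2, with all libraries, gave an adjusted p of 0.000381. The table does not separate reads of an introduced Met sequence from those of the mouse gene. Hgf (ENSMUSG00000028864), which encodes the ligand of Met, fell 2.93-fold from 7.22 ± 0.233 to 2.47 ± 0.336 CPM (adjusted p = 0.00108). Ctnnb1 (ENSMUSG00000006932), which encodes beta-catenin, rose 1.65-fold from 110 ± 8.33 to 182 ± 26.7 CPM (adjusted p = 0.00682). As the labels do not expand CAT, whether reads of an introduced sequence are counted with Ctnnb1 is unknown. Alb (ENSMUSG00000029368), which encodes albumin, fell 1.21-fold from 65490 ± 609 to 54240 ± 246 CPM (adjusted p = 0.000727). Mki67 (ENSMUSG00000031004), a marker of dividing cells, rose 2.81-fold from 2.92 ± 0.186 to 8.18 ± 0.0993 CPM (adjusted p = 0.000857). The 26 cell cycle genes split into 7 risen and 8 fallen, the same adjusted over the list alone (camera adjusted p = 0.839). The S/G2 cyclin Ccna2 rose from 1.05 ± 0.0687 to 3.70 ± 0.855 CPM, while the G1 cyclin Ccnd1 fell from 122 ± 1.99 to 43.6 ± 0.546 CPM and the replication gene Mcm6 fell from 14.2 ± 0.565 to 4.66 ± 0.596 CPM.

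**Figure D2:**
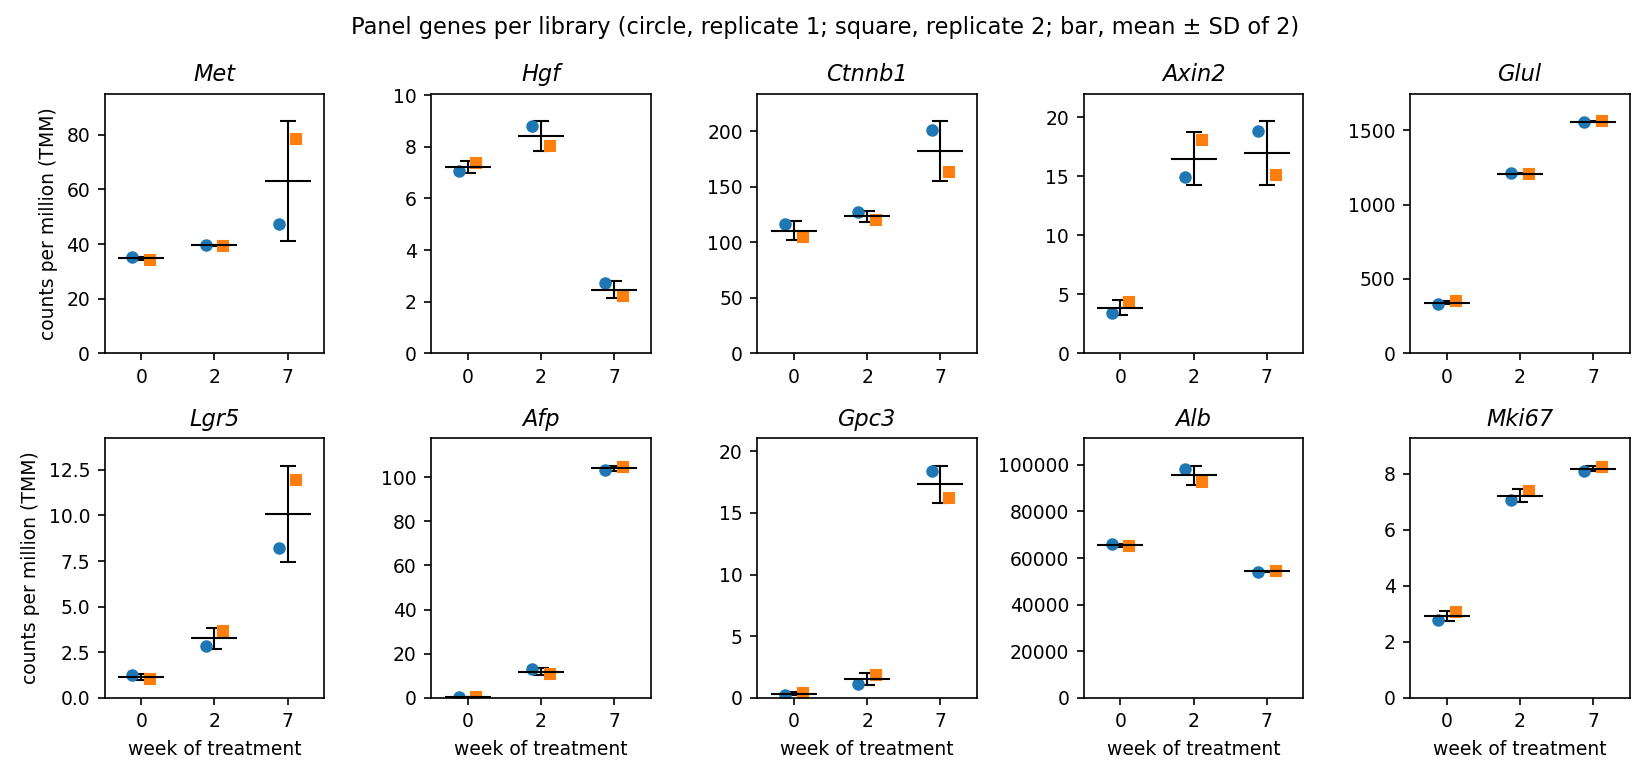
TMM-scaled CPM (y axes, linear, from 0) of the 10 panel genes against week of treatment (x axes). Points are the 2 libraries of a week and bars their mean ± SD; week 2 libraries are typed as female and the others as male. Afp reaches 104 CPM at week 7, and Met lies at 62.96 ± 21.98 CPM at week 7, with its libraries apart.

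Among 15 genes of the unfolded protein and amino acid stress response, 0 rose and 9 fell at week 7 against week 0, or 2 and 10 adjusted over the list alone, with a median log2 fold change of -0.734 (camera adjusted p = 9.98e-05; adjusted p = 0.164 with an estimated correlation). Creld2 fell 4.30-fold from 220 ± 1.92 to 51.2 ± 6.20 CPM, and the chaperone gene Dnajb9 fell 2.82-fold from 201 ± 7.94 to 71.2 ± 4.78 CPM. Of 7 Kupffer cell markers 0 rose and 6 fell, or 0 and 7 adjusted over the list alone, with a median of -0.612 (camera adjusted p = 9.98e-05; adjusted p = 0.164 with an estimated correlation). Clec4f fell from 147 ± 1.10 to 97.8 ± 5.39 CPM and Marco fell 1.96-fold from 7.10 ± 0.460 to 3.63 ± 0.318 CPM. Stellate cell and fibroblast markers had 1 risen and 5 fallen of 10, or 2 and 7 adjusted over the list alone, with a median of -0.65 (camera adjusted p = 0.00779; adjusted p = 0.203 with an estimated correlation). Lrat, which makes the retinyl esters stored in stellate cells, fell 4.38-fold from 32.4 ± 0.741 to 7.41 ± 0.630 CPM, and Reln rose from 33.1 ± 1.57 to 53.2 ± 0.296 CPM. Interferon response genes had 4 risen and 0 fallen of 19, or 8 and 1 adjusted over the list alone (median 0.485, camera adjusted p = 0.00621; adjusted p = 0.254 with an estimated correlation). Usp18 rose 12.0-fold from 0.860 ± 0.309 to 10.3 ± 1.86 CPM. The interferon call was lost without week 0 replicate 2 (adjusted p = 0.0717).

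Sex-biased liver genes also moved between these male-typed weeks. Of 13 female-biased genes 6 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median log2 fold change of 3.31 (camera adjusted p = 0.000173; adjusted p = 0.254 with an estimated correlation). Cyp2b9 rose 25.1-fold from 1.201 ± 0.0861 to 30.1 ± 0.283 CPM (edgeR adjusted p = 4.33e-09), against 385 ± 1.71 CPM in the female-typed week 2 libraries. Of 13 male-biased genes 1 rose and 7 fell, or 1 and 8 adjusted over the list alone, with a median of -0.312 (camera adjusted p = 0.00779; adjusted p = 0.203 with an estimated correlation). Hsd3b5 fell 1.34-fold from 256 ± 8.41 to 191 ± 2.72 CPM, and Elovl3, the member that rose, went from 25.7 ± 0.492 to 38.9 ± 3.12 CPM (adjusted p = 0.00786; 0.0516 without week 0 replicate 1 and 0.0688 without week 7 replicate 1). Cyp3a16, at 12.7 ± 1.13 CPM after 9 counts at week 0, was called (adjusted p = 0.0111) but not without week 7 replicate 1 or 2 (0.0684 and 0.0734). Hao2, chosen after its values were seen, had 8 counts over both week 0 libraries and 467 at week 7 (adjusted p = 0.0115), and its call was lost in the same way (0.0723 and 0.0769).

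The naming rule takes only genes with a mean of at least 5 CPM in the higher group. Among these, the largest called increases from week 0 to week 7, beside Afp and Dlk1, were in Car4, Sfrp2, Mogat2, Akr1c18, Apcdd1 and Cpe. Car4, a carbonic anhydrase gene, had 0 counts at week 0 and 20.5 ± 0.0596 CPM at week 7, at least 83.8-fold higher, and Sfrp2, which encodes a secreted Wnt-binding protein, was at least 42.7-fold higher at 10.4 ± 1.16 CPM. The largest called decreases under the same rule were in Cyp26b1, Depp1, Mup22, Lrat, Creld2, Ankrd55, Syvn1 and Nek7. Depp1 fell 9.95-fold from 134 ± 3.63 to 13.5 ± 4.33 CPM, and Nek7 fell 3.31-fold from 68.0 ± 0.0956 to 20.5 ± 1.10 CPM. With the replicate block the calls of Cpe and Cyp26b1 were lost (edgeR adjusted p = 0.0501 and 0.0579). Fits to only the 4 libraries compared lost Cyp26b1 and Syvn1 (0.0513 and 0.0598), and no filter lost Syvn1 (0.0652). The calls of Cpe, Cyp26b1, Mup22 and Syvn1 (log2 fold changes of 7.30, -5.56, -3.31 and -1.78) were also lost without certain libraries. There the log2 fold changes were 7.24 to 7.36, -5.58 to -5.54, -3.40 to -3.22 and -1.83 to -1.73. Without either replicate of week 0 for Cpe, Mup22 and Syvn1, or of week 7 for Cyp26b1, they were called. Cpe had an adjusted p of 0.0652 without week 7 replicate 1 and 0.0591 without replicate 2, and for Mup22, a member of a near-identical family, these were 0.0518 and 0.0519. Cyp26b1 had 0.0809 and 0.08 without week 0 replicate 1 or 2 and 0.0587 and 0.0596 without week 2 replicate 1 or 2. Syvn1 had 0.0738 and 0.0749 without week 2 replicate 1 or 2, and 0.168 and 0.169 without week 7 replicate 1 or 2.

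In all, edgeR called 2123 of 15368 genes between week 7 and week 0, 1165 higher and 958 lower, of which 375 and 144 changed by over 2-fold. The balance of directions depended on the scaling, with 1321 higher and 784 lower with total counts only, and 1069 and 1076 with upper-quartile scaling. At an adjusted p under 0.01 there were 1008, and 283 when tested against a fold change of 1.5. Without week 0 replicate 1 or 2 there were 1328 or 1380, and without week 7 replicate 1 there were 1298. Without week 7 replicate 2, 773 were higher. The other lists were not called by camera in this comparison. The urea cycle had 1 risen and 3 fallen of 7, hepatocyte plasma proteins 5 and 8 of 22, bile acid genes 3 and 7 of 17, and drug-metabolising P450 genes 2 and 7 of 14. Fatty acid synthesis had 5 risen and 4 fallen of 14, fatty acid oxidation 4 and 3 of 19, cholesterol synthesis 5 and 7 of 18, glycolysis 5 and 2 of 17, and gluconeogenesis 2 and 2 of 8. NRF2 targets had 4 risen and 1 fallen of 14, acute phase genes 5 and 2 of 16, p53 targets 2 and 3 of 12, and extracellular matrix genes 1 and 3 of 15. Gstm3 rose 4.01-fold from 55.0 ± 1.66 to 220.5 ± 0.699 CPM, and Lcn2, an acute phase gene, rose 13.4-fold from 1.91 ± 0.0895 to 25.4 ± 1.83 CPM. Macrophage and monocyte markers had 0 risen and 4 fallen of 14, T and NK cell markers 0 and 0 of 11, B and plasma cell markers 0 and 1 of 7, and neutrophil markers 0 and 0 of 6. Liver endothelial markers had 0 risen and 1 fallen of 12, cholangiocyte markers 1 and 0 of 6, and erythroid markers 0 and 0 of 4. Their camera adjusted p lay between 0.0564 and 0.842. The P450 list was called without week 7 replicate 2 (adjusted p = 0.0447), and with limma voom so were the P450 (0.00629), cholesterol (0.0241) and NRF2 (0.0241) lists. With no filter these 3 were called too (0.0437, 0.0437 and 0.0304), and with upper-quartile scaling the P450 and NRF2 lists were (0.0495 each). Adjusted over the list alone, these 20 lists had between 0 and 6 risen and between 0 and 10 fallen genes. Krt19, a bile duct keratin, rose 8.95-fold from 0.513 ± 0.330 to 4.60 ± 0.109 CPM.

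**Figure D3:**
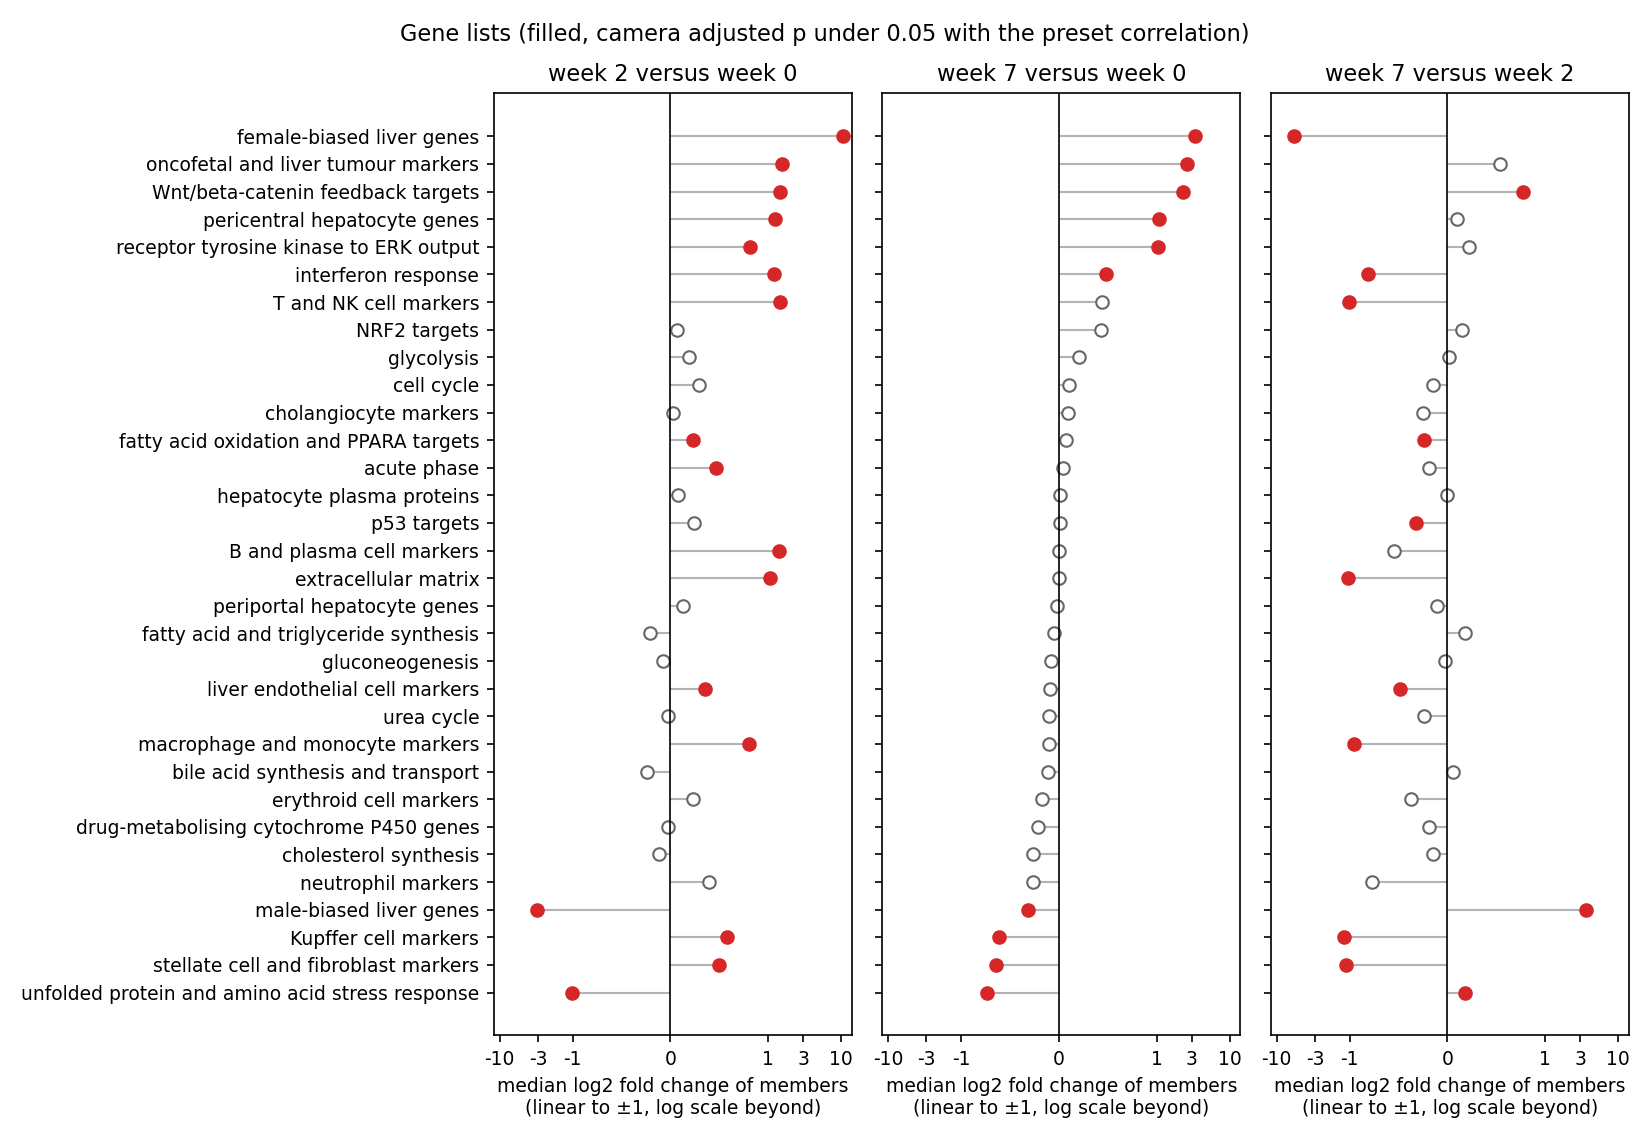
Median log2 fold change of the measured members of each of 32 gene lists (x axes, linear to ±1 and logarithmic beyond, genes at 0 counts set to their bound) in the 3 comparisons of weeks. Filled points have a camera adjusted p under 0.05 with the preset correlation, which 17, 10 and 13 lists had; with an estimated correlation 0 had. Both comparisons with week 2 also differ in sex.

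Week 2 differed from week 0 in the sex typing as well as in time. All 13 female-biased genes were higher and all 13 male-biased genes lower at week 2, also adjusted over the list alone, with median log2 fold changes of 10.5 and -3.09 (camera adjusted p = 4.7e-13 and 4.7e-17; adjusted p = 0.0865 and 0.0838 with an estimated correlation). Cyp2b9 went from 1.201 ± 0.0861 to 385 ± 1.71 CPM, and Cyp4a12a fell 261-fold from 370 ± 3.81 to 1.42 ± 0.0240 CPM. In these female-typed week 2 libraries 10 of 14 Wnt targets, 14 of 16 pericentral genes and 10 of 17 tumour markers were higher too (adjusted p = 0.0895, 0.0865 and 0.0895 with an estimated correlation). Afp rose 28.5-fold to 11.9 ± 1.51 CPM (edgeR adjusted p = 3.95e-08) and Axin2 rose 4.25-fold to 16.5 ± 2.25 CPM (adjusted p = 8.11e-05).

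The Wnt feedback list had 10 risen and 1 fallen of 14 at week 2 against week 0, the same adjusted over the list alone (median 1.45, camera adjusted p = 0.000128; adjusted p = 0.0895 with an estimated correlation). Nkd1 rose 9.77-fold to 38.0 ± 2.01 CPM, Lgr5 rose 2.85-fold to 3.27 ± 0.574 CPM (adjusted p = 0.00518), and Dkk4, a secreted Wnt antagonist, fell from 1.64 ± 0.530 CPM to 0 counts, at least 8.13-fold lower. With limma voom the calls of Lgr5 and Dkk4 were lost (adjusted p = 0.0766 and 0.0512), as were those of Gpc3 (0.096), Uty (0.0537) and Mup-ps19 (0.0551). The pericentral list had 14 risen and 2 fallen of 16, the same adjusted over the list alone (median 1.23, camera adjusted p = 1.81e-09; adjusted p = 0.0865 with an estimated correlation). Glul rose 3.55-fold to 1208 ± 4.36 CPM, and Cyp2e1 fell 1.23-fold from 5946 ± 67.9 to 4823 ± 90.4 CPM. Oncofetal markers had 10 risen and 0 fallen of 17, or 11 and 0 adjusted over the list alone (median 2.20, or 1.56 with bounds, camera adjusted p = 1.29e-06; adjusted p = 0.0895 with an estimated correlation). Gpc3 was 4.62-fold higher at 1.51 ± 0.511 CPM (adjusted p = 0.00223). The ERK output list had 7 risen and 0 fallen of 15, or 9 and 0 adjusted over the list alone (median 0.81, camera adjusted p = 4.37e-05; adjusted p = 0.0936 with an estimated correlation), with Phlda1 3.08-fold higher at 135 ± 1.35 CPM. Unfolded protein response genes had 0 risen and 10 fallen of 15, or 2 and 10 adjusted over the list alone (median -1.02, camera adjusted p = 4.92e-05; adjusted p = 0.0865 with an estimated correlation), and Hyou1 fell 3.87-fold from 231 ± 14.4 to 59.7 ± 1.27 CPM. Met at 39.5 ± 0.338 CPM, Hgf at 8.42 ± 0.568 CPM and Ctnnb1 at 123 ± 5.03 CPM were not called (adjusted p = 0.694, 0.474 and 0.371). Alb rose 1.46-fold to 95490 ± 4074 CPM and Mki67 2.47-fold to 7.22 ± 0.228 CPM.

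Many matrix, macrophage, Kupffer, stellate and endothelial cell genes were higher at week 2 than at week 0, in libraries whose sex also differs, while 0 of 6 neutrophil markers were called (camera adjusted p = 0.519). Of 15 extracellular matrix genes 12 rose and 0 fell, the same adjusted over the list alone (median 1.07, camera adjusted p = 1.37e-07; adjusted p = 0.0865 with an estimated correlation), and the collagen gene Col3a1 rose 2.88-fold from 27.7 ± 0.423 to 79.9 ± 0.228 CPM. Interferon response genes had 13 risen and 0 fallen of 19, or 16 and 0 adjusted over the list alone (median 1.19, camera adjusted p = 1.75e-08; adjusted p = 0.0865 with an estimated correlation), and Cxcl9 rose 4.99-fold from 7.67 ± 0.734 to 38.3 ± 1.42 CPM. Macrophage and monocyte markers had 7 risen and 0 fallen of 14, or 10 and 0 adjusted over the list alone (median 0.807, camera adjusted p = 4e-06; adjusted p = 0.0865 with an estimated correlation). Kupffer cell markers had 5 risen and 0 fallen of 7, or 6 and 0 adjusted over the list alone (median 0.575, camera adjusted p = 0.00199; adjusted p = 0.109 with an estimated correlation). Stellate cell and fibroblast markers had 5 risen and 1 fallen of 10, or 6 and 1 adjusted over the list alone (median 0.496, camera adjusted p = 0.00706; adjusted p = 0.132 with an estimated correlation). Liver endothelial markers had 4 risen and 0 fallen of 12, or 6 and 0 adjusted over the list alone (median 0.358, camera adjusted p = 0.00229; adjusted p = 0.132 with an estimated correlation). C1qa, a complement gene of macrophages, rose 1.64-fold to 124 ± 1.83 CPM, Clec4f 1.36-fold to 199.7 ± 2.70 CPM and Lyve1 2.26-fold to 11.4 ± 0.471 CPM. T and NK cell markers had 0 called of 11 (median 1.47, camera adjusted p = 0.0103; adjusted p = 0.132 with an estimated correlation, and camera adjusted p = 0.0591 without week 2 replicate 1), and B and plasma cell markers had 0 called of 7 (median 3.55, or 1.41 with bounds, camera adjusted p = 0.00405; adjusted p = 0.211 with an estimated correlation). No member of either list was called adjusted over the list alone. Their levels were low, with Cd3g at 0.662 ± 0.056 and 1.97 ± 0.432 CPM and Cd79a at 0.0518 ± 0.0733 and 0.772 ± 0.0541 CPM. Cd3g (adjusted p = 0.0658) would be called without week 7 replicate 1 or 2 (0.0443 and 0.0493), and Cd79a (0.0693) without week 0 replicate 2 (0.0229) or with DESeq2 (0.00882).

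Acute phase genes had 10 risen and 4 fallen of 16 at week 2, the same adjusted over the list alone (median 0.463, camera adjusted p = 0.000944; adjusted p = 0.0936 with an estimated correlation). Lcn2 rose 16.5-fold to 31.5 ± 0.335 CPM, while the haptoglobin gene Hp fell 1.46-fold from 1829 ± 8.94 to 1255 ± 9.78 CPM. Fatty acid oxidation and PPARA target genes had 12 risen and 1 fallen of 19, the same adjusted over the list alone (median 0.23, camera adjusted p = 0.000945; adjusted p = 0.132 with an estimated correlation), and Cyp4a10 rose 54.2-fold from 15.9 ± 1.80 to 863 ± 9.37 CPM. Other metabolic genes called at week 2 included Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 2.09-fold higher at 150 ± 6.08 CPM, and Cyp7b1, 5.72-fold lower at 79.9 ± 1.38 CPM. Cyp7b1 is also in the male-biased list, all members of which were lower in these female-typed libraries. The remaining 15 lists were not called by camera, although p53 targets were without week 2 replicate 1 (adjusted p = 0.0378) or with no filter (0.041), and cell cycle genes without week 0 replicate 2 (0.045). The bile acid list, with 4 risen and 9 fallen of 17 (4 and 10 adjusted over the list alone; camera adjusted p = 0.0606), was called with limma voom (0.0204). Among the genes with the largest fold changes under the naming rule, those higher included Cyp3a41b, Hsd3b1, Car4, Sult2a6, Sult2a1, Eci3 and Cyp3a16, and lower were Ddx3y, Eif2s3y, Cyp4a12b, Kdm5d, Uty, Cyp4a12a, Mup-ps19 and Capn8. Car4, with 0 counts at week 0 and 25.5 ± 1.79 CPM at week 2, was at least 104-fold higher. The call of Cyp3a41b was lost without either week 0 or either week 2 library (adjusted p = 0.0598 and 0.0575 without week 0 replicate 1 or 2, and 0.17 and 0.166 without week 2 replicate 1 or 2).

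In all, 2862 of 15368 genes were called between week 2 and week 0, 1508 higher and 1354 lower, of which 572 and 310 changed by over 2-fold. With libraries scaled to total counts only, the split was 2007 higher and 913 lower, and the median log2 fold change of all genes was 0.105 in place of 0.0137. At an adjusted p under 0.01 there were 1574 calls, and 663 against a fold change of 1.5, while there were 1801 and 1826 without week 2 replicate 1 or 2. Without week 0 replicate 1, 807 were lower.

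From week 2 to week 7, that is from female-typed to male-typed libraries, Afp rose a further 8.72-fold (edgeR adjusted p = 1.4e-07), Gpc3 11.4-fold (adjusted p = 4.43e-05) and Lgr5 3.08-fold (adjusted p = 0.00234). Axin2 was at 16.5 ± 2.25 and 17.0 ± 2.68 CPM, a difference that was not called (adjusted p = 0.91), and its sign turned with upper-quartile scaling, with total counts only, and without week 2 or week 7 replicate 1 (log2 fold changes of -0.01235, -0.01231, -0.08832 and -0.1284). Glul rose 1.29-fold (adjusted p = 7.36e-05), Hgf fell 3.41-fold (adjusted p = 0.000277) and Alb fell 1.76-fold (adjusted p = 1.4e-06). Mki67 was not called (adjusted p = 0.537), nor was Met (0.144), which was called with DESeq2 (0.00702). The log2 fold change of Met was 0.673, or 0.991 without week 7 replicate 1. Ctnnb1 was 1.48-fold higher (adjusted p = 0.0126), but not called without week 2 replicate 1 or 2 (0.0609 and 0.0926). At week 7, 11 of 15 matrix genes were lower than at week 2, as were 8 of 14 macrophage, 7 of 7 Kupffer, 7 of 10 stellate and 5 of 12 endothelial cell markers (adjusted p between 0.124 and 0.18 with an estimated correlation).

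The Wnt feedback list had 7 risen and 0 fallen of 14 from week 2 to week 7, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.000441; adjusted p = 0.132 with an estimated correlation), and Apcdd1, a membrane-bound Wnt inhibitor, rose from 0.369 ± 0.0506 to 19.6 ± 0.7003 CPM. Extracellular matrix genes had 1 risen and 11 fallen of 15, the same adjusted over the list alone (median -1.11, or -1.07 with bounds, camera adjusted p = 2.89e-07; adjusted p = 0.124 with an estimated correlation). Col3a1 fell 4.40-fold to 18.2 ± 2.74 CPM, and the fibronectin gene Fn1, the member that rose, went to 1128 ± 47.3 CPM (adjusted p = 0.0117). The Fn1 call was lost with upper-quartile scaling (0.0633), with total counts only (0.0967), without week 2 replicate 1 or 2 (0.09 and 0.0706) and without week 7 replicate 1 (0.0534). Kupffer cell markers had 0 risen and 7 fallen of 7, macrophage and monocyte markers 0 and 8 of 14, stellate cell and fibroblast markers 0 and 7 of 10, and liver endothelial markers 0 and 5 of 12. Adjusted over the list alone these were 0 and 7, 0 and 8, 0 and 8, and 0 and 7. Their camera adjusted p-values were 7.7e-06, 1.6e-05, 4.25e-05 and 0.000459; with an estimated correlation the adjusted p was 0.124 for Kupffer cells, 0.124 for macrophages and monocytes, 0.124 for stellate cells and 0.18 for endothelial cells. Marco fell 4.21-fold, C1qa 2.30-fold, Dcn 2.19-fold to 55.9 ± 3.54 CPM and Clec4g 1.62-fold to 62.8 ± 2.03 CPM. Interferon response genes had 0 risen and 8 fallen of 19, or 1 and 11 adjusted over the list alone (camera adjusted p = 0.000726; adjusted p = 0.18 with an estimated correlation), with Gbp2 2.35-fold lower at 7.80 ± 0.892 CPM. Fatty acid oxidation genes had 2 risen and 13 fallen of 19, or 2 and 14 adjusted over the list alone (camera adjusted p = 0.000638; adjusted p = 0.18 with an estimated correlation), with Cyp4a10 29.8-fold lower at 29.0 ± 1.48 CPM. All 13 male-biased genes rose and all 13 female-biased genes fell, also adjusted over the list alone (camera adjusted p = 3.76e-15 and 2.39e-10; adjusted p = 0.0996 and 0.124 with an estimated correlation).

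The calls of 3 further lists from week 2 to week 7 were lost with fewer libraries, with medians in the same direction. Unfolded protein response genes had 5 risen and 1 fallen of 15, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0253; adjusted p = 0.186 with an estimated correlation), and without week 2 or week 7 replicate 1 the camera adjusted p was 0.152 and 0.0757 and the median 0.124 and 0.147, against 0.179; with counts divided by 4 that p was 0.0525. The p53 targets had 0 risen and 3 fallen of 12, or 0 and 6 adjusted over the list alone (camera adjusted p = 0.0169; adjusted p = 0.181 with an estimated correlation), and without week 2 or week 7 replicate 2 the camera adjusted p was 0.0575 and 0.0608 and the median -0.269 and -0.371, against -0.318. T and NK cell markers had 0 risen and 1 fallen of 11, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.0478; adjusted p = 0.224 with an estimated correlation), and without week 2 or week 7 replicate 1 the camera adjusted p was 0.161 and 0.0956 and the median -0.839 and -1.10, against -1.02. That p was 0.0762 with upper-quartile scaling, 0.0731 with total counts only, 0.0659 with limma voom and 0.0515 with at least 10 counts in every library of a group. Its fallen member was Cd3g (edgeR adjusted p = 0.042), with 0.102, 0.233 and 0.169 without week 2 replicate 1 or 2 or week 7 replicate 1. Among the genes with the largest fold changes under the naming rule, those higher at week 7 were Ddx3y, Eif2s3y, Kdm5d, Cyp4a12b, Uty, Mup-ps19, Cyp4a12a and Capn8, and those lower included Xist, Sult2a1, Eci3, Sult2a4, Sult2a2, Sult2a5 and Slc22a26. Xist, at 218 ± 3.25 CPM in week 2, was at least 956-fold lower at week 7. In all, 3040 of 15368 genes were called, 1545 higher and 1495 lower, of which 336 and 501 changed by over 2-fold. The balance turned with the scaling, to 1258 higher and 1799 lower with upper-quartile scaling and 1248 and 1784 with total counts only. Without week 7 replicate 1 or 2, 1019 and 999 were higher. There were 1632 at an adjusted p under 0.01, 585 against a fold change of 1.5, and 1842 and 1923 without week 2 replicate 1 or 2.

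Over the 3 weeks together, 4064 of 15368 genes differed at any time, and 1807 of 14701 without the week 2 libraries, where the test is that of week 7 against week 0 on 4 libraries. Of the genes called against week 0, 555 were higher and 384 lower at both later weeks, and 205 were called in opposite directions. Without week 0 replicate 1 there were 448 higher and 218 lower at both, and with total counts only 690 and 265. Independent lists of these sizes would share 114.3 and 84.4. Both comparisons use the same week 0 libraries, which raises such counts. The covariance of the log2 fold changes across genes was 1.05, against a mean of 0.172 and a highest value of 0.189 in simulations of unchanged groups. Their correlation was 0.55, against a mean of 0.501 and a highest value of 0.531. In fits that gave each comparison its own week 0 library, 563 and 565 genes were called in the same direction, 115 and 112 in opposite directions, and independent lists would share 87.06 and 84.59. The correlation of the log2 fold changes was then 0.246 and 0.265. Between week 2 and week 7, 660 of the genes called higher and 634 of those called lower at week 2 changed back, without being called in the week 2 direction at week 7. Independent lists would share 146.7 and 136.1. With a week 2 library of its own for each comparison, 699 and 681 genes changed back, against 104.8 and 107.8 from independent lists. These 1294 genes were 769 and 839 in number without week 2 replicate 1 or 2; the week 2 libraries, common to both comparisons, differ in sex from the rest.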

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

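The tests of library composition and of immunoglobulin variable genes were set before their results were seen, and the others after. Lists whose change from week 0 differed between week 7 and week 2, by camera on the difference itself, are given as the median log2 change from week 2 to week 7, and sex differed with time in each. Those higher at week 7 were male-biased liver genes (3.63), Wnt feedback targets (0.775) and the unfolded protein response (0.179). Lower were female-biased liver genes (-5.74), Kupffer cell markers (-1.19), extracellular matrix (-1.11), stellate cell and fibroblast markers (-1.11), T and NK cell markers (-1.02), macrophage and monocyte markers (-0.953), interferon response genes (-0.813), liver endothelial markers (-0.487), p53 targets (-0.318) and fatty acid oxidation genes (-0.24). With an estimated correlation 0 of these lists passed, 8 of the 32 lists had an unadjusted p under 0.05, and fry called 23.

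Of the genes called at week 2 against week 0, 1294 changed back by week 7 (769 and 839 without week 2 replicate 1 or 2). Without any composition factor 1310 genes did so, within 1.5 times the reported number. This total cannot decide whether composition has a part, because a composition shift moves calls between directions. At week 2 against week 0, 1508 higher and 1354 lower genes became 2007 and 913 without that factor. Of the 2862 calls there, 2421 were kept in their direction. The albumin and Mup shares also differed at week 2. The sex of the mice remains open for these 1294 genes. The lists of sex-biased genes met what it needs, with a highest camera adjusted p of 2.39e-10 over the 4 tests. All 4 were lost with an estimated correlation (adjusted p between 0.0838 and 0.124). Such lists would differ in any case once week 2 is typed as female. They therefore do not tell whether sex accounts for the 1294 genes. For the 939 genes called in the same direction at both later weeks, sex is argued against for the week 7 change, because week 7 was male-typed like week 0. With a week 0 library of its own for each comparison, such genes were 6.47 and 6.68 times as many as independent lists give. They were 4.90 and 5.04 times those called in opposite directions. This excess does not exclude sex for the week 2 change, because sex-biased genes also moved in the week 2 direction at week 7. There, 6 of 13 female-biased genes rose and 7 of 13 male-biased genes fell. Anything that both week 0 libraries have in common stays open for part of the 939 genes. Time of treatment and sex cannot be separated for any single gene in the comparisons with week 2, and a biological effect of treatment at week 2 stays untested. At week 7 such an effect cannot be told apart from age, because no untreated mice of that week were included.

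Female-biased genes were higher at week 7 than at week 0, between libraries both typed as male. RNA from female mice in the week 7 libraries is argued against: the median member stood at 1.85% of its week 2 rise, which would bring Xist to 4.05 CPM, and Xist had 0 counts, where the floor is at most 0.235 CPM. A shift away from male-type transcription stays open as a hypothesis: 7 of 13 male-biased genes fell (camera adjusted p = 0.00779; adjusted p = 0.203 with an estimated correlation), but Elovl3 rose and the Mup share did not fall (10.4% and 10.1% at week 0, 10.4% and 11.5% at week 7). Reads shared between near-identical genes stay open for the Cyp2, Cyp3a and Sult members, because of the 5 members outside those families only 1 was higher past the threshold, but 4 had a fold change above 0 (median log2 of 2.32). The 1 that passed, Hao2, rose from 8 to 467 counts over both libraries (log2 fold change 5.73, edgeR adjusted p = 0.0115), which sharing with those families would not give, though its call was lost without week 7 replicate 1 or 2 (log2 fold changes of 5.805 and 5.658, adjusted p = 0.0723 and 0.0769).

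Replicates of a week differed by a robust SD of 0.0522 to 0.0755 among abundant genes, where counting gives 0.0263 to 0.0268. Whether they may come from 1 animal or 1 RNA pool was tested on antibody variable genes, which differ from animal to animal. These gave a lowest within-week Spearman rho of 0.14 and a highest between-week rho of 0.374 over 20 genes, so separate animals and a shared source cannot be told apart at this depth, where a library held 16 to 838 such counts. The median rho was 0.208 within and -0.229 between weeks, but weeks differed: the week 7 pair had 0.724, while the pairs of weeks 0 and 2 had 0.208 and 0.14 against 0.0397 to 0.374 between these weeks. For the closeness of replicates no biological explanation was tested.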

How the results depend on the processing

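Counts divided by 4 and the fit without the week 2 libraries were tried only after the data were seen. The scalings, the filters, DESeq2, limma voom, the fits to the 4 libraries compared and counts divided by 4 kept each count they gave of called genes, of the 939 genes shared and of lists called by camera within 1.5 times; DESeq2 gave no list tests, and fits to 4 libraries no count for any time. Over all alternatives and comparisons, list results kept their side of the threshold in 1528 cases, which include lists never called. They lost a call in 53, gained one in 44 and turned in 1, and the estimated correlation gave 40 of the 53 losses. Named genes kept their side in 5575 cases, lost a call in 198, gained one in 16 and turned in 11. Apart from the panel, the rule names genes by a small p or a large fold change, which favours kept calls. An adjusted p under 0.01 left 1574 genes for week 2 against week 0, 1008 for week 7 against week 0, 1632 for week 7 against week 2 and 2194 at any time, and a test against a fold change of 1.5 left 663, 283 and 585, as stricter thresholds must. Without the week 2 libraries, 1807 genes differed at any time, since a group is missing. Leaving out each library in turn gave 1801 to 2752 genes for week 2 against week 0, lowest without week 2 replicate 1 (1801) or 2 (1826), 1298 to 1856 for week 7 against week 0, lowest without week 7 replicate 1 (1298) or week 0 replicate 1 (1328) or 2 (1380), and 1842 to 2961 for week 7 against week 2, lowest without week 2 replicate 1 (1842) or 2 (1923); a group of 1 is then assumed to vary like the others. With an estimated correlation camera called 0, 0 and 0 lists in the 3 comparisons (12, 7 and 8 at an unadjusted p under 0.05), and fry, which asks another question, called 27, 19 and 23. The lowest camera adjusted p with an estimated correlation was 0.0838, for male-biased genes at week 2, of which all 13 fell. The loss of a call with that setting thus does not tell weak lists from strong ones, although its adjusted p at week 2 ran from 0.0838 to 0.973. Axin2 between week 2 and week 7 turned to -0.01235 with upper-quartile scaling and -0.01231 with total counts, and to -0.08832 and -0.1284 without week 2 or week 7 replicate 1, with 0.195 as the highest value over left-out libraries. Ighg1 at week 2 against week 0, at -0.01 in the reported fit, was 0.01958 with upper-quartile scaling, 0.0824 with total counts, 0.04247 with the replicate block, 0.02774 with counts divided by 4, 0.2139 with limma voom, 0.09168 without week 2 replicate 2 and 1.114 without week 0 replicate 1 (called, adjusted p = 0.0317), and -0.6263 was the lowest value over left-out libraries. Hepatocyte plasma proteins at week 2 (median 0.0773) were called lower by fry (adjusted p = 0.0278) and not called by camera; the cause was not tested.

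Replicate numbers recur in each week, and a replicate block gave 2436, 1702 and 2620 genes in the 3 comparisons, 3488 at any time, an overlap of 780 and 17, 10 and 13 lists. Same-numbered libraries did not deviate together (correlations of -0.0019, -0.0146 and -0.013), so the number pairs nothing here. Depth limits low genes most, as 12 counts are only 3 read pairs.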

Other observations

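The genes described here were chosen after their values were seen, and no test of an explanation was run on them. The metallothionein genes, whose products bind zinc and copper, were higher at both later weeks. Mt1 had 12.5 ± 0.245 CPM at week 0, 377 ± 2.80 at week 2 and 99.7 ± 0.230 at week 7 (SD, n = 2), and Mt2 had 4.18 ± 0.0140, 219 ± 4.81 and 45.8 ± 2.02 CPM, with edgeR adjusted p-values of 4.33e-09 and 1.73e-08 for week 7 against week 0. Transcripts of the imprinted Dlk1 and Meg3 region, of which Dlk1 and Meg3 are also in the oncofetal list, were higher as well. Meg3 went from 0.102 ± 0.0313 to 4.83 ± 0.765 and 7.15 ± 0.209 CPM, and the neighbouring noncoding gene Rian from 0.615 ± 0.274 to 11.6 ± 1.75 and 22.5 ± 1.56 CPM (adjusted p = 8.97e-06 and 9.47e-06 for week 7 against week 0). These directions held under all 4 scalings, which shifted the fold changes too little to turn them. The log2 fold change of Meg3 at week 7 against week 0 ran from 6.075 to 6.135. The heat shock genes Hspa1a and Hspa1b, which share most of their sequence, were low at week 2. Hspa1b had 106 ± 1.47 CPM at week 0, 13.3 ± 0.838 at week 2 and 93.2 ± 3.07 at week 7, and Hspa1a had 37.5 ± 1.70, 4.94 ± 0.468 and 41.4 ± 2.16 CPM; week 2 also differed in sex.

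The immunoglobulin genes Igkc and Ighg1 were higher at week 7 than at week 0. The kappa light chain gene Igkc had 3.21 ± 0.409 CPM at week 0, 9.11 ± 0.885 at week 2 and 36.1 ± 0.296 at week 7 (adjusted p = 2.08e-06 for week 7 against week 0), and the IgG1 heavy chain gene Ighg1 had 0.858 ± 0.656, 0.855 ± 0.0876 and 31.9 ± 2.10 CPM (adjusted p = 0.00396). The IgM heavy chain gene Ighm had 2.695 ± 0.382, 6.33 ± 0.0188 and 4.997 ± 1.34 CPM (adjusted p = 0.0451). The Ighm call was lost without week 0 replicate 1 or 2 (0.191 and 0.0827), week 2 replicate 1 or 2 (0.0776 and 0.078) or week 7 replicate 1 (0.244). Directions at week 7 held under all 4 scalings, which here too shifted the fold changes too little to turn them. The difference of Ighg1 at week 2 turned with the scaling, and its log2 fold change was 1.11 without week 0 replicate 1. The B and plasma cell marker list, which holds no antibody gene except Jchain, was not called at week 7 (camera adjusted p = 0.359). Apart from any group, the mitochondrial gene mt-Nd4 had 251339 counts in week 0 replicate 1 and 258892 in week 7 replicate 2, against 3004 and 2756 in their partners and 3602 and 3451 at week 2.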
